A study of Mus musculus with 8 samples.

How the data were processed

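The data were 8 RNA-seq libraries from mouse spleen B cells, 4 in each of 2 groups, that the submitters' labels describe as follicular B cells enriched with an isolation kit and then sorted by flow cytometry. The gate is given in the labels as positive for B220, CD93, CD21 and CD23. Both groups carried the Rosa26GFPZFP36L1 allele per the labels, and the group named GFP-ZFP36L1 here also carried CD23cre in the heterozygous state. The series title sets GFP-ZFP36L1 expressing cells against wild type, so Cre and expression of the protein go together in this design and their effects are not separated. Replicate numbers were given in accession order, which is also the order of the numbers 1 to 8 in the sample titles, and were not used to pair libraries across groups. The labels do not say whether the libraries of a group came from separate animals, so p-values measure the spread between these libraries.

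Libraries were made with a stranded mRNA kit and sequenced as paired reads of 100 bp, per the labels. Trim Galore, TopHat2 2.0.12, HTSeq and DESeq2 1.10.1 are named with build GRCm38 in the submitters' processing notes, which give no order or settings in the sources used here. The strand setting of the gene counting is not given in the sources used here. The authors deposited a table of raw counts per gene for 43629 Ensembl genes, and these whole-number counts were the basis of every test. The authors also deposited normalized values per gene, read here as a signal because the raw count divided by this value was 1 constant per library, with relative departures of at most 5.7e-10. That table was used only for this check. The deposited comparison table gives the authors' mean signal, log2 fold change and p-value per gene. Its log2 values were compared with those computed here, and its p-value columns were used to count the authors' calls. All 8 count columns were mapped to a library through the sample titles, 0 columns were left unmapped and 0 entries named no gene.

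Gene coordinates and 3' UTRs came from GENCODE mouse release 21, which uses GRCm38. Gene symbols came from the same release or, for identifiers it lacks, from a separate list of gene names. Together these gave a symbol for 42548 of the 43629 identifiers. The 3' UTR of a gene was the longest stretch after an annotated stop codon in its transcripts, and 100.00% of these stretches were preceded by a stop codon. The motif UAUUUAU, the core site bound by proteins of the ZFP36 family, was counted as TATTTAT on the sense strand.

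Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, libraries were scaled by TMM factors, and groups were compared with edgeR's quasi-likelihood test with robust dispersion and Benjamini-Hochberg adjustment, with group as the sole term. An adjusted p under 0.05 was called. Levels are counts per 1000000 (CPM) on TMM-scaled library sizes, given as mean ± SD of 4 libraries, and fold changes are group GFP-ZFP36L1 over control. Standard errors of log2 fold changes were obtained from the F statistic.

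A total of 33 gene lists were fixed before the data were examined. The 29 lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Members were also adjusted over the list alone. Per-library scores, the mean log2 CPM of a list, were compared by an exact permutation test over the 70 assignments of 4 libraries, which allows no two-sided p below 0.0286. Genes with a heptamer were compared with other genes having a 3' UTR by camera and by 10000 draws matched in 20 strata of 3' UTR length and 5 of expression. The draws were one-sided for lower values. The other 20 orders of 5 T and 2 A served as control heptamers, and each of the 21 orders was set against 1000 matched draws.

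Named genes followed a rule fixed before the data were examined. It takes Zfp36l1, Zfp36, Zfp36l2, Klf2, Irf8, Fcer2a, Cr2, Cd1d1, Notch2, Cd93 and Gt(ROSA)26Sor always. It adds the 12 largest positive and 12 largest negative log2 fold changes among called genes of at least 5 CPM whose groups did not overlap, leaving out immunoglobulin V, D and J segments, predicted and RIKEN genes and pseudogenes. It adds the members with the smallest p in each list, up to 4. Some members that the rule takes are not reported here.

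Alternatives were DESeq2 1.42.0, limma voom with quality weights, RLE and upper-quartile factors, no filter, a filter of 1 CPM in 4 libraries, a fit without the robust prior, 1 surrogate variable from sva 3.50.0, removal of immunoglobulin segments, and each library left out in turn. Removal of a smooth trend with transcript length and GC, by splines with 5 degrees of freedom per library, was added after the data were seen, as was the number in the sample title as a linear term. All 35 splits of the 8 libraries into 4 and 4 were refitted.

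The procedure was tested on simulated counts for this comparison, with the means, library sizes and dispersions of the 12925 genes that passed the filter there. Of genes changed 2 times, 87.9% were recovered, against 73% of those changed 1.5 times and 28.8% of those changed 1.25 times. There were 6 false calls among 129. With no change planted, 1 gene and 0 lists were called. With 1 list shifted by a log2 value of 0.2, 1 other list was called too. A planted shift of -0.05 in the heptamer genes gave a camera p of 3.48e-07. Genes were drawn independently of each other, so the simulation cannot show how often sets are called falsely where genes vary together.

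Library totals ran from 38947758 to 51024233 counts, which limits precision for genes near 1 CPM. Pairs of libraries within a group differed by a chi-square of 7.02 to 61.7 per degree of freedom, so no library was a repeat of another within sampling noise.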

Results

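RNA was measured in 8 libraries of sorted mouse splenic follicular B cells, the recirculating B cells of the lymphoid follicle. ZFP36L1 is an RNA-binding protein that binds AU-rich elements in 3' UTRs and promotes mRNA decay. Both groups carried a GFP-ZFP36L1 allele at the Rosa26 locus, and 4 libraries also carried a Cre recombinase driven from CD23, a gene switched on in mature B cells. The comparison asks how the transcriptome of follicular B cells differs when GFP-ZFP36L1 is expressed. Control replicates 1 to 4 held 43285538, 51024233, 42742853 and 40976668 counts, and GFP-ZFP36L1 replicates 1 to 4 held 43929445, 48328512, 42053501 and 38947758. The totals did not differ by more than their spread (exact permutation p = 0.657, two-sided, n = 4 each). Component 1 of a principal component analysis held 37.3% of the variance. GFP-ZFP36L1 replicate 4 lay at 33.0 on it and control replicate 1 at -23.1, while GFP-ZFP36L1 replicate 1 lay at -7.54, within the range of the controls. In each group it rose with the number in the sample titles, at -23.1, -12.9, -6.85 and -3.26 in control replicates 1 to 4 and -7.54, 7.38, 13.3 and 33.0 in GFP-ZFP36L1 replicates 1 to 4.

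Zfp36l1 itself was lower, not higher, in the libraries labelled GFP-ZFP36L1. Its level was 547 ± 35.1 CPM in the controls and 439 ± 28.6 CPM in the labelled libraries (SD, n = 4 each), and the highest labelled library, at 470.7 CPM, lay below the lowest control, at 523.1 CPM. The noncoding gene Gt(ROSA)26Sor, which marks the Rosa26 locus used for the allele, had 16.9 ± 2.58 CPM in the controls and 3.91 ± 0.604 CPM in the labelled libraries, a log2 fold change of -2.11 ± 0.14 (SE). Trappc5, a subunit gene of a vesicle-tethering complex whose locus adjoins the gene for CD23, Fcer2a, was higher at 99.2 ± 9.20 against 66.6 ± 4.09 CPM. Fcer2a had 1212 ± 117 CPM in the labelled libraries and 1460 ± 69.5 CPM in the controls. Because Zfp36l1 ran against what the label leads one to look for, groups are named below by their labels. Levels set against each other below give the labelled libraries first and the controls after.

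Zfp36l1 (ENSMUSG00000021127) lies on chromosome 12 from 80107754 to 80113013 on the minus strand of GRCm38, and its 3' UTR of 1835 nt holds 3 UAUUUAU heptamers. Its log2 fold change was -0.32 ± 0.07 (SE), with an adjusted p of 0.0348 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Leaving out any library except GFP-ZFP36L1 replicate 1 ended that call, with adjusted p from 0.0701 to 0.105 in the same test. The antisense gene Gm26669 overlaps 4967 bp of it, and the strand setting of the counting was not given. The table holds 1 count per gene, so transcripts of the allele and of the endogenous gene were not separated. Gt(ROSA)26Sor (ENSMUSG00000086429) lies on chromosome 6 from 113067428 to 113077333 on the minus strand and shares 846 bp with Thumpd3 on the other strand. Its adjusted p was 4.14e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and Thumpd3 had a log2 fold change of -0.12 ± 0.05 (SE). Trappc5 (ENSMUSG00000040236, chromosome 8, 3676299 to 3681255, plus strand) and Fcer2a (ENSMUSG00000005540, chromosome 8, 3681737 to 3694175, minus strand) are separated by 482 bp. The log2 fold change of Trappc5 was 0.58 ± 0.07 (SE), with a Benjamini-Hochberg adjusted p of 0.00253 in edgeR's quasi-likelihood test, and that of Fcer2a was -0.27 ± 0.08 (SE), adjusted p 0.102. Fcer2a passed under 5 of 19 alternatives.

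**Figure D1:**
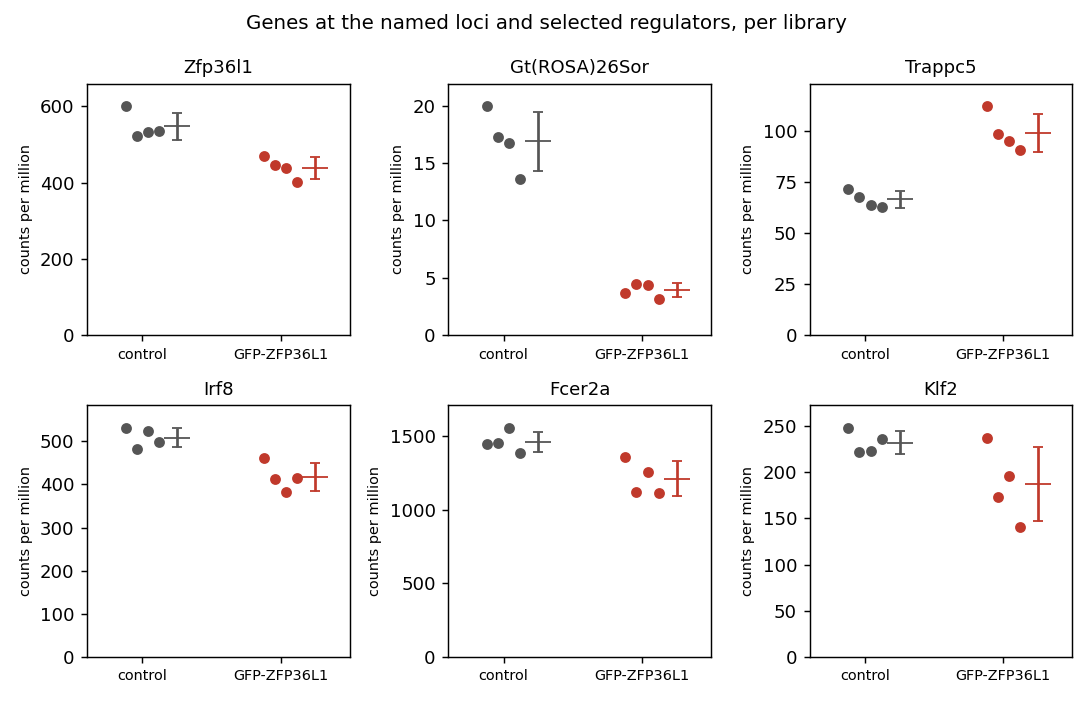
Level in CPM of Zfp36l1, Gt(ROSA)26Sor, Trappc5, Irf8, Fcer2a and Klf2 in each library (points) with the group mean and SD (bars), n = 4 per group. Zfp36l1 lay between 523.1 and 599.4 CPM in the controls and between 401.8 and 470.7 CPM in the libraries labelled GFP-ZFP36L1.

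The paralogs Zfp36 and Zfp36l2 had log2 fold changes of -0.12 ± 0.07 and -0.28 ± 0.10 (SE). Irf8, a transcription factor of the B cell lineage, was lower in the labelled libraries, at 418 ± 31.8 against 509 ± 22.6 CPM. Klf2, a regulator of lymphocyte trafficking, had 187 ± 40.1 against 232 ± 12.3 CPM. Notch2, the receptor needed for marginal zone fate, had 521 ± 16.2 against 615 ± 66.4 CPM. The marginal zone genes Cr2 and Cd1d1 had log2 fold changes of 0.08 ± 0.08 and -0.06 ± 0.05 (SE). Cd93, the gene for a marker of the gate as labelled, was low in both groups, at 11.3 ± 2.86 CPM in the labelled libraries and 10.5 ± 2.003 CPM in the controls. Cd93 is also a member of the transitional and precursor list, and the labels do not say why a gate for follicular cells is positive for its protein. Irf8 overlaps the annotated gene Gm20388 on the same strand over 20337 bp, so its counts are uncertain to that extent. Of the genes in this paragraph, only Irf8 was called, with an adjusted p of 0.0456 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. That call was lost, with an adjusted p of up to 0.149 in the same test, when any library except GFP-ZFP36L1 replicate 1 was left out. Of the genes not called, Notch2 passed under 6 of 19 alternatives, and Klf2 and Zfp36l2 under 1 each.

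Across the transcriptome, 407 of 13035 tested genes passed the threshold, 238 higher and 169 lower in the labelled libraries. Genes that were higher were mostly weakly expressed, with a median level of 6.44 CPM and a median log2 fold change of 0.62, and included Gbp8, Kif13a, Myof, Lurap1 and Rtl5. Genes that were lower had a median level of 51.1 CPM and a median log2 fold change of -0.39, and included Gad1, Rapgef4, Ccr6 and Stac2. A change of 1.5 times or more was seen in 128 of the higher and 42 of the lower genes.

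Among called genes of at least 5 CPM whose groups did not overlap, and with predicted and RIKEN genes, pseudogenes and immunoglobulin segments left out, the largest increase was in Gbp8, an interferon-inducible guanylate-binding protein, at 9.03 ± 3.31 against 2.95 ± 0.234 CPM, a fold of 3.06. Below 5 CPM, 8 called genes without overlap had larger log2 fold changes, from 1.645 to 2.173. Of these, Myo1h, Tmem205, Rhobtb1, Ccser1 and Apba1, chosen after their values were seen, each lost the call without 1 or more of the libraries other than GFP-ZFP36L1 replicate 1, at adjusted p of up to 0.131. The rest, Rragd, Ifit1bl2 and Steap4, also chosen after their values were seen, kept the call with any 1 library left out. Their adjusted p were then at most 0.0356 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of genes below 5 CPM that fell, Cxcr3 and 1700028I16Rik, the latter chosen after its values were seen, changed by more than Gt(ROSA)26Sor, at -2.589 and -2.129. The call of Cxcr3 was lost without GFP-ZFP36L1 replicate 2 or control replicate 1, 3 or 4, and that of 1700028I16Rik without GFP-ZFP36L1 replicate 3 or control replicate 2 or 3, at adjusted p of up to 0.0649 and 0.0599. Kif13a, a kinesin motor of endosome transport, rose from 3.17 ± 0.179 to 9.37 ± 2.99 CPM. Myof, encoding the membrane-repair protein myoferlin, had 54.1 ± 17.8 against 22.4 ± 2.47 CPM. Lurap1, Rtl5 and the chemokine receptor gene Ccr1 rose by log2 fold changes of 1.03 ± 0.11, 1.03 ± 0.11 and 1.02 ± 0.19 (SE). Ifit1, an interferon-induced antiviral gene, had 10.5 ± 3.19 against 5.37 ± 1.06 CPM. Abi2, a regulator of actin assembly, Esr1, the estrogen receptor alpha gene, and the semaphorin receptor gene Plxnd1 had log2 fold changes of 0.88 ± 0.10, 0.86 ± 0.12 and 0.85 ± 0.15 (SE). Mcoln3, a lysosomal cation channel, and Slc25a24, a mitochondrial carrier, rose by 0.83 ± 0.10 and 0.83 ± 0.08 (SE). The adjusted p of the 12 largest increases of at least 5 CPM, Gbp8 to Slc25a24, ran from 0.00141 for Lurap1 and Slc25a24 to 0.0392 for Ifit1 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The call of Myof was lost with no filter or without any 1 of the controls, that of Ccr1 without control replicate 2, 3 or 4, that of Plxnd1 without control replicate 3, and that of Ifit1 with no filter, with 1 surrogate variable, with the title number as a linear term or without any library except GFP-ZFP36L1 replicate 1. Over all alternatives their highest adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment or the tool replacing it were 0.0881, 0.0723, 0.0629 and 0.121.

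Among the genes that were lower, Gad1, a glutamate decarboxylase, had 6.84 ± 2.84 against 18.8 ± 2.89 CPM. Rflnb, a filamin-binding protein, had 35.1 ± 11.2 against 72.6 ± 1.27 CPM. Rapgef4, a cAMP-activated exchange factor for Rap GTPases, had 31.1 ± 2.81 against 63.4 ± 7.22 CPM. Ccr6, the receptor for the chemokine CCL20, had 76.0 ± 18.6 against 152 ± 14.1 CPM. Stac2, the lipid transfer gene Pltp and the hexose transporter gene Slc2a6 had log2 fold changes of -0.87 ± 0.12, -0.77 ± 0.09 and -0.76 ± 0.12 (SE). Ankrd37 and Hsd11b1, the latter a glucocorticoid-activating enzyme, had -0.74 ± 0.14 and -0.69 ± 0.16 (SE). Nlrc3, an NLR family member, and Txnrd1, a thioredoxin reductase, had -0.65 ± 0.07 and -0.55 ± 0.09 (SE). The adjusted p of these genes ran from 0.000547 for Rapgef4 to 0.0469 for Hsd11b1 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The calls of Gad1, Rflnb and Hsd11b1 were lost with no filter or without GFP-ZFP36L1 replicate 2 or 3 or any control, and that of Ankrd37 without GFP-ZFP36L1 replicate 3 or control replicate 2 or 3. Over all alternatives their highest adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment or the tool replacing it were 0.0978, 0.11, 0.139 and 0.0719.

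**Figure D2:**
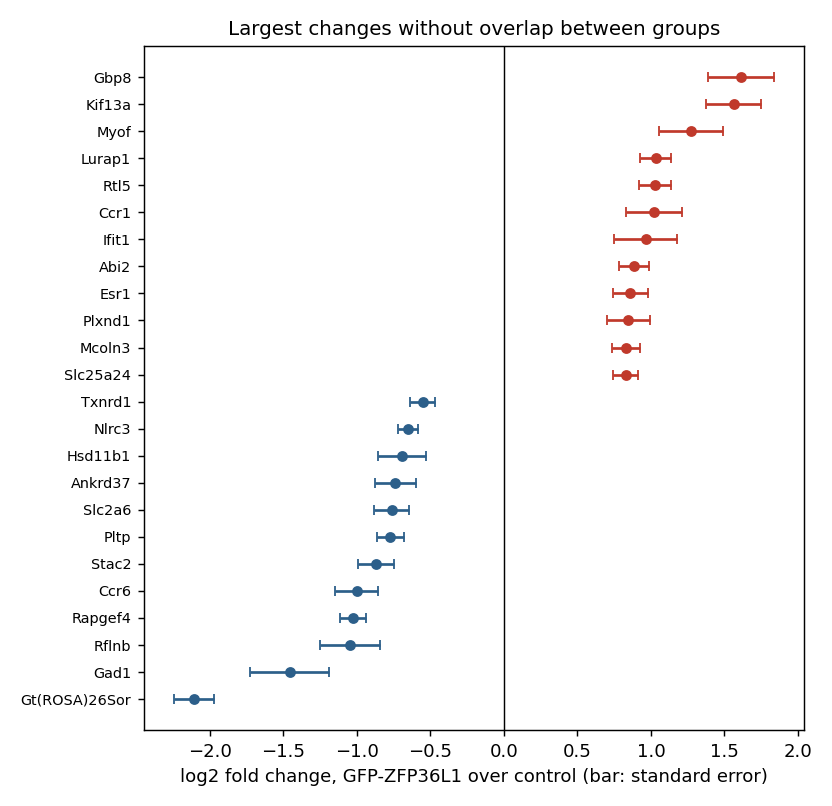
Log2 fold change, libraries labelled GFP-ZFP36L1 over control, of the 12 largest increases and 12 largest decreases among called genes of at least 5 CPM whose groups did not overlap (points, n = 4 per group), with standard errors (bars). Predicted and RIKEN genes, pseudogenes and immunoglobulin segments were left out. The values drawn run from -2.11 for Gt(ROSA)26Sor to 1.61 for Gbp8.

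The groups did not overlap in 402 of the 407 called genes. Of all tested genes, 11.2% had no overlap, where chance gives 2.86%. At an unadjusted p under 0.05 there were 2260 genes. The count of called genes was 240, 100, 79 and 134 without control replicates 1 to 4 in turn, and 948, 166, 120 and 233 without GFP-ZFP36L1 replicates 1 to 4. It was 882 with DESeq2, 1064 with limma voom, 1315 with a surrogate variable and 1030 with the title number as a linear term.

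The follicular B cell list was lower, with all 15 measured members at a negative log2 fold change and a median of -0.26. Cd55, a complement regulator, had 582 ± 53.6 against 809 ± 40.1 CPM, and Ighd, the IgD constant gene, 2522 ± 226 against 3173 ± 65.9 CPM. In all, 3 members fell by edgeR's quasi-likelihood test, Cd55 and Ighd among them, the other 12 did not pass, and 6 were lower when adjusted over the list alone. Il4ra had a log2 fold change of -0.28 ± 0.08 (SE). The list's adjusted p was 6.9e-05 by camera with Benjamini-Hochberg adjustment, and adjusted p = 0.532 with an estimated correlation. The per-library score was 8.77 ± 0.143 against 8.99 ± 0.0142, with no overlap and an exact permutation p of 0.0286, the smallest that 4 against 4 libraries can give, or 0.138 after Benjamini-Hochberg adjustment over the 29 lists. Without GFP-ZFP36L1 replicate 1, 6 members were called, and without any 1 of GFP-ZFP36L1 replicates 2 to 4 or control replicates 2 to 4 only 1 was.

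The marginal zone list moved in both directions: Myof was higher, while Rasgrp2, at 493 ± 45.1 against 622 ± 13.3 CPM, and Asb2, at 0.489 ± 0.134 against 1.01 ± 0.192 CPM, were lower. The other 17 of its 20 members did not pass, and 4 were higher and 3 lower when adjusted over the list alone. Its camera adjusted p was 0.927 with Benjamini-Hochberg adjustment, and its median log2 fold change was 0.05. In the germinal centre list Lmo2, a transcriptional adaptor, was lower by -0.41 ± 0.06 and the plexin gene Plxnb2 higher by 0.55 ± 0.12 (SE), with the other 8 of 10 members not passing, 1 higher and 2 lower when adjusted over the list alone, and an adjusted p of 0.401 by camera with Benjamini-Hochberg adjustment. In the plasma cell list Fkbp11 was lower, by -0.83 ± 0.17 (SE), 12 of 13 members did not pass, and 1 was higher and 2 lower when adjusted over the list alone. In the B1 cell list Itgam, at 3.41 ± 0.725 against 1.96 ± 0.335 CPM, was the sole called member of 11, and 3 were higher and 3 lower when adjusted over the list alone. No member of the transitional and precursor list passed edgeR's quasi-likelihood test, where 3 of 10 had an unadjusted p under 0.05, DESeq2 called 2 and limma voom 3, and 1 was lower when adjusted over the list alone. Sox4 and Myb, its members with the smallest p, had log2 fold changes of -0.46 ± 0.13 and 0.57 ± 0.19 (SE). Camera gave the plasma cell, B1 and transitional lists adjusted p of 0.954, 0.927 and 0.567 with Benjamini-Hochberg adjustment. Called members numbered 0 in the marginal zone list without control replicate 2, 3 or 4 and 1 without GFP-ZFP36L1 replicate 2 or 4, 1 in the germinal centre list without GFP-ZFP36L1 replicate 3 or any control, and 0 in the plasma cell list without GFP-ZFP36L1 replicate 2 or 3 or any control. Without GFP-ZFP36L1 replicate 1 the plasma cell, B1 and transitional lists had 2, 4 and 1, the B1 list had 0 without any other library, and the transitional list had 1 without control replicate 1.

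Interferon response genes were higher as a list, with 23 of 26 members at a positive log2 fold change and a median of 0.52. Irf7, the main regulator of the interferon response, had 81.4 ± 15.8 against 53.1 ± 2.98 CPM and Rtp4 26.1 ± 4.19 against 18.2 ± 1.19 CPM, and both rose, as did Ifit1. Gbp3, another guanylate-binding gene of the list, fell, at 61.5 ± 4.55 against 79.96 ± 3.54 CPM. The other 22 members did not pass, and 11 were higher and 1 lower when adjusted over the list alone. DESeq2 called 10 members and limma voom 8, against 4 in edgeR's quasi-likelihood test. Camera gave the list an adjusted p of 3.71e-05 with Benjamini-Hochberg adjustment, and adjusted p = 0.708 with an estimated correlation. The scores of GFP-ZFP36L1 replicates 2, 3 and 4 were 4.97, 4.71 and 5.19, above every control, while replicate 1 at 4.39 lay within the controls, which ran from 4.35 to 4.60 (exact permutation p = 0.0571, two-sided, n = 4 each). Without GFP-ZFP36L1 replicate 1, 13 members were called, and with any other library left out between 1 and 3. The call of Irf7 was also lost with no filter and with the title number as a linear term.

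Reported target mRNAs of the ZFP36 family were lower as a list. Of 41 tested members, 7 fell and 0 rose: the cytokine gene Tnf (14.3 ± 1.14 against 19.5 ± 2.19 CPM), Zfp36l1, the cell cycle genes E2f2 and Ccne1, the kinase genes Pim1 and Plk2, and Irf8. Zfp36l1 is also the gene carried by the allele, whose transcripts were not separated from the endogenous ones, and the list was not tested without it. E2f2 had 49.9 ± 6.15 against 64.1 ± 3.29 CPM and Pim1 43.8 ± 5.64 against 57.2 ± 3.54 CPM. The other 34 did not pass, and 10 were lower when adjusted over the list alone. The median log2 fold change was -0.05, with 14 members positive and 27 negative. Camera gave an adjusted p of 0.0107 with Benjamini-Hochberg adjustment, and adjusted p = 0.532 with an estimated correlation, while fry, which asks whether the members move on balance in 1 direction, gave 0.0187. The per-library score was 5.595 ± 0.05326 against 5.678 ± 0.02315 (exact permutation p = 0.0286, or 0.138 after Benjamini-Hochberg adjustment over the 29 lists). The calls were sensitive to single libraries: 10 members were called without GFP-ZFP36L1 replicate 1, and between 0 and 2 when any other library was left out.

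The G1 to S list shared E2f2 and Ccne1 with the targets, and these were its only called members of 29, and the same number were lower when adjusted over the list alone. Its median log2 fold change was -0.02, at an adjusted p of 0.313 by camera with Benjamini-Hochberg adjustment, while its per-library score was 4.143 ± 0.0197 against 4.237 ± 0.02963, with no overlap (exact permutation p = 0.0286, or 0.138 after Benjamini-Hochberg adjustment over the 29 lists). In the mitotic list Kif23, a kinesin of cytokinesis, was higher by 0.37 ± 0.09 (SE), while 19 of 20 members did not pass, and 1 was higher and 2 lower when adjusted over the list alone. Bbc3, the pro-apoptotic gene encoding PUMA, rose from 1.85 ± 0.303 to 3.39 ± 0.378 CPM and Ccng1 from 90.9 ± 7.07 to 112 ± 9.51 CPM in the p53 list, where Plk2 fell, 13 of 16 did not pass, and 2 were higher and 3 lower when adjusted over the list alone. Bbc3 was also the sole called member of the 23 apoptosis regulators, of which 2 were higher when adjusted over the list alone. Xiap, next in that list, had a log2 fold change of 0.20 ± 0.06 (SE). The calls of Kif23, Ccng1 and Plk2 were also lost without the robust prior, that of Kif23 with no filter and after the length and GC correction, and that of Plk2 with upper-quartile factors, a filter of 1 CPM and immunoglobulin segments removed. Camera gave the mitotic, p53 and apoptosis lists adjusted p of 0.986, 0.954 and 0.828 with Benjamini-Hochberg adjustment. The G1 to S list had 0 called members without GFP-ZFP36L1 replicate 2 or 4 or control replicate 2, 3 or 4 and 1 without GFP-ZFP36L1 replicate 3 or control replicate 1, and the mitotic list had 0 without any library except GFP-ZFP36L1 replicate 1. The p53 list had 0 without GFP-ZFP36L1 replicate 3 or control replicate 2 and 1 without GFP-ZFP36L1 replicate 2 or control replicate 3 or 4, and the apoptosis list had 0 without GFP-ZFP36L1 replicate 3 or control replicate 2 and 3 without GFP-ZFP36L1 replicate 1.

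Migration and adhesion genes were lower as a list, at an adjusted p of 0.0178 by camera with Benjamini-Hochberg adjustment, and adjusted p = 0.708 with an estimated correlation. In all, 3 members fell, among them Ccr6 and Cxcr3, a chemokine receptor gene near the detection limit at 0.0922 ± 0.0944 against 0.566 ± 0.203 CPM, while the integrin gene Itgam rose. The other 20 of 24 members did not pass, and 2 were higher and 6 lower when adjusted over the list alone. The per-library score was 6.768 ± 0.09172 against 6.944 ± 0.02545 (exact permutation p = 0.0286, or 0.138 after Benjamini-Hochberg adjustment over the 29 lists). Camera no longer called the list without GFP-ZFP36L1 replicate 4 (adjusted p 0.087 with Benjamini-Hochberg adjustment) or control replicate 2 (0.119). Its called members were 1 without GFP-ZFP36L1 replicate 2 or control replicate 3 or 4, and 2 without GFP-ZFP36L1 replicate 4 or control replicate 2. In the NF-kB list, the activation marker gene Cd83, at 154 ± 7.54 against 199 ± 21.8 CPM, and Tnf fell, 18 of 20 members did not pass, and 2 were lower when adjusted over the list alone, at an adjusted p of 0.959 by camera with Benjamini-Hochberg adjustment. The NF-kB list had 0 called members without any 1 of GFP-ZFP36L1 replicates 2 to 4 or control replicate 3, and 1 without any other control. The Notch list had no called member of 19 in edgeR's quasi-likelihood test, with 6 at an unadjusted p under 0.05, 2 called by DESeq2, 2 by limma voom, and 1 lower when adjusted over the list alone. Without GFP-ZFP36L1 replicate 1 or 4 or control replicate 1 it had 1. Its member with the smallest p was the glycosyltransferase gene Lfng, at 36.5 ± 8.004 against 55.8 ± 5.91 CPM with an adjusted p of 0.0505 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The adjusted p of the Notch list was 0.959 by camera with Benjamini-Hochberg adjustment. In the Notch, NF-kB, mitotic, apoptosis, erythroid and myeloid lists the median, the mean or the direction of the test differed in sign.

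The B cell receptor, antigen presentation, immunoglobulin constant and V segment lists were lower by camera. Camera with Benjamini-Hochberg adjustment gave B cell receptor signalling genes an adjusted p of 0.0178 and antigen presentation genes 0.00135 (adjusted p = 0.708 with an estimated correlation for each), with medians of -0.08 and -0.12. No single member of either was called by edgeR's quasi-likelihood test, where 6 of 26 and 7 of 20 had an unadjusted p under 0.05, DESeq2 called 1 and 2, limma voom called 3 and 2, and 0 passed in either when adjusted over the list alone. In each list, 1 member was called without GFP-ZFP36L1 replicate 1. The per-library scores of the B cell receptor, antigen presentation, constant and V segment lists had exact permutation p of 0.2, 0.0571, 0.0286 and 0.286 (two-sided, n = 4 each), or 0.437, 0.207, 0.138 and 0.437 after Benjamini-Hochberg adjustment over the 29 lists. Camera lost the B cell receptor list without GFP-ZFP36L1 replicate 3 or 4, at adjusted p of 0.145 and 0.0727 with Benjamini-Hochberg adjustment, and also with the title number as a linear term. Cd22, an inhibitory coreceptor, had 1772 ± 67.7 against 2080 ± 77.0 CPM, and H2-Oa and H2-Ob, genes of class II antigen loading, had log2 fold changes of -0.19 ± 0.06 and -0.19 ± 0.06 (SE). All 8 immunoglobulin constant genes had negative values with a median of -0.27, and Ighg1, of the switched isotype IgG1, fell to 0.589 ± 0.161 from 1.84 ± 0.450 CPM, together with Ighd, while 4 were lower when adjusted over the list alone. Without any library except GFP-ZFP36L1 replicate 1, 1 of the constant genes was called. Ighm, chosen after its values were seen, had 5165 ± 260 against 5413 ± 323 CPM. The constant genes' adjusted p was 0.000515 by camera with Benjamini-Hochberg adjustment, and adjusted p = 0.532 with an estimated correlation. Of 211 V segments, which share reads between near-identical copies, Igkv4-63 fell and Ighv9-3 rose, with a list median of -0.06, an adjusted p of 0.0192 by camera with Benjamini-Hochberg adjustment (adjusted p = 0.902 with an estimated correlation), and 0 passing when adjusted over the list alone. That call was lost without GFP-ZFP36L1 replicate 2 or 4 or control replicate 2, at adjusted p of 0.093, 0.51 and 0.298 by camera, and also with the title number as a linear term and after the length and GC correction, where the direction turned (0.147). The call of Ighv9-3 was lost with no filter, and the 2 calls became 0 without any 1 of GFP-ZFP36L1 replicates 2 to 4 or control replicate 2 or 3, and 1 without control replicate 1 or 4.

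Cytosolic ribosomal protein genes and oxidative phosphorylation genes had slightly negative values nearly throughout, in 83 of 84 and 68 of 73 members, with medians of -0.13 and -0.10. Rpl3 had 1167 ± 113 against 1327 ± 67.6 CPM, and Atp5b, of the ATP synthase, 430 ± 55.7 against 511 ± 16.5 CPM. Camera gave adjusted p of 1.15e-06 and 9.4e-05 with Benjamini-Hochberg adjustment, and with an estimated correlation adjusted p = 0.902 for both. No member of either passed edgeR's quasi-likelihood test, where 3 and 10 had an unadjusted p under 0.05, DESeq2 called 1 and 0, limma voom called 0 and 2, and 0 passed when adjusted over the list alone. Their called members were 1 and 4 without GFP-ZFP36L1 replicate 1. Camera lost the oxidative phosphorylation list without GFP-ZFP36L1 replicate 4 or control replicate 1, at adjusted p of 0.0658 and 0.104 with Benjamini-Hochberg adjustment. The share of counts in ribosomal protein genes was 6.49% ± 0.665 against 6.86% ± 0.628 (SD, n = 4, exact permutation p = 0.457). The slope of log2 CPM per doubling of transcript length was 0.0129 ± 0.0158 in the labelled libraries and -0.0129 ± 0.0193 in the controls (exact permutation p = 0.0857), with GFP-ZFP36L1 replicate 4 at 0.0363 and control replicate 1 at -0.0395. Glycolysis genes had no called member of 17 by edgeR's quasi-likelihood test or by DESeq2, with 6 at an unadjusted p under 0.05, 2 called by limma voom, 4 without GFP-ZFP36L1 replicate 1 and 0 adjusted over the list alone. Their adjusted p was 0.32 by camera with Benjamini-Hochberg adjustment. Hk1 and Ldha, at its head, had log2 fold changes of 0.20 ± 0.06 and -0.21 ± 0.08 (SE).

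**Figure D3:**
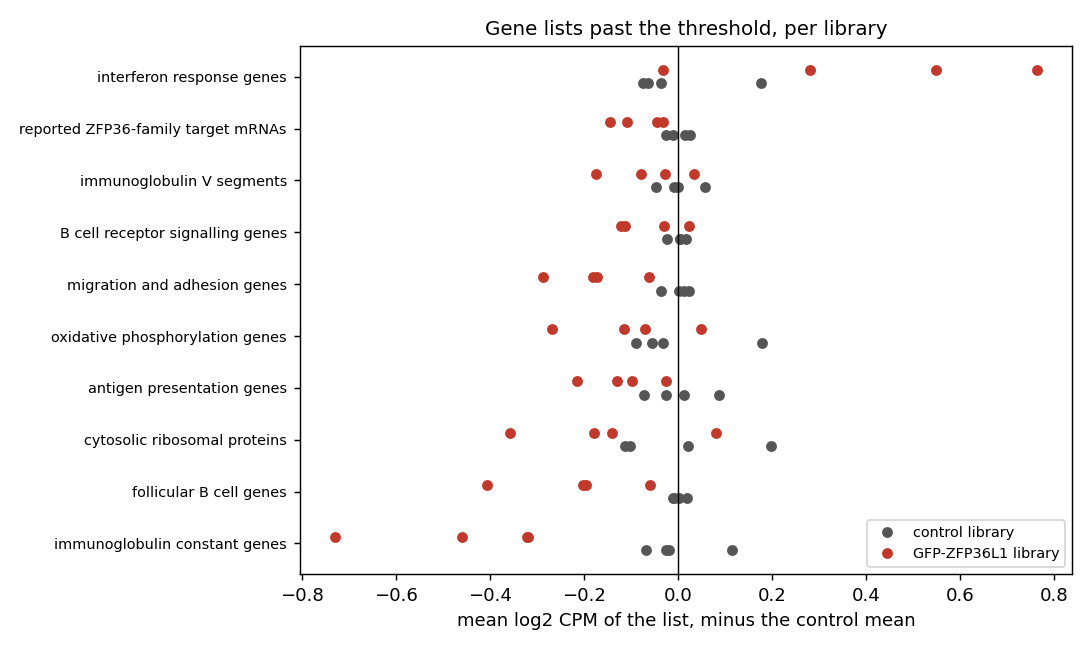
Mean log2 CPM of each list called by camera, minus the mean of the controls, in each library (grey, control; red, GFP-ZFP36L1; n = 4 each). The groups did not overlap for the follicular list, while the interferon score of GFP-ZFP36L1 replicate 1, at 4.39, lay among the controls and those of the other 3 lay above them.

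Immediate early and stress genes had no called member of 23 in edgeR's quasi-likelihood test, with 8 at an unadjusted p under 0.05, 1 called by DESeq2, 1 by limma voom, 0 adjusted over the list alone and an adjusted p of 0.986 by camera with Benjamini-Hochberg adjustment. Without GFP-ZFP36L1 replicate 1 or control replicate 1, 1 was called. Nr4a1 and Btg2 had log2 fold changes of -0.24 ± 0.07 and -0.23 ± 0.08 (SE). CCR4-NOT and mRNA decay genes, the machinery that ZFP36 proteins recruit, had no called member of 30 in that test, 4 at an unadjusted p under 0.05, 1 by DESeq2, 1 by limma voom, 0 adjusted over the list alone and 3 without GFP-ZFP36L1 replicate 1. Their adjusted p was 0.959 by camera with Benjamini-Hochberg adjustment, and Cnot6l, a deadenylase gene, had a log2 fold change of 0.17 ± 0.05 (SE). Of the 9 tested genes listed around Rosa26, Gt(ROSA)26Sor alone was called, with a list median of -0.06, 2 lower when adjusted over the list alone, adjusted p of 0.0581 by camera and 0.00351 by fry with Benjamini-Hochberg adjustment, and a score without overlap (exact permutation p = 0.0286, or 0.138 after adjustment over the 29 lists). Of the 13 listed around Fcer2a, Trappc5 alone was called, with a median of -0.05, 1 higher and 1 lower when adjusted over the list alone, and an adjusted p of 0.954 by camera with Benjamini-Hochberg adjustment. These lists had 2 and 3 called members without GFP-ZFP36L1 replicate 1. The list tests and the score for Rosa26 include Gt(ROSA)26Sor itself, so they do not show a change of the other genes listed there. Outside the lists, but within 500 kb, Ttll3 near Gt(ROSA)26Sor fell, by -0.2846 ± 0.06694, and Pex11g near Trappc5 rose, by 0.621 ± 0.1503 (SE), both chosen after their values were seen. Their adjusted p were 0.0447 and 0.0486 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The call of Ttll3 was lost without any library except control replicate 1 and that of Pex11g without any except GFP-ZFP36L1 replicate 1, at adjusted p of up to 0.148 for each.

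Markers of other cells the gate could admit did not pass, with the exceptions of Itgam and Pecam1. Of 7 monocyte, macrophage and granulocyte markers, Itgam alone rose, while the macrophage gene Adgre1 had 1.73 ± 0.650 against 3.21 ± 0.574 CPM. Lyz2, a highly expressed gene of those cells that was chosen after its values were seen, had 0.687 ± 0.133 against 0.756 ± 0.186 CPM. Among T cell markers Lck had 34.0 ± 0.431 against 32.5 ± 1.27 CPM and Lat 2.22 ± 0.493 against 1.58 ± 0.365 CPM. Tbx21, in the natural killer list, had 1.37 ± 0.405 against 2.74 ± 0.852 CPM. Bst2, in the dendritic list and also induced by interferon, had 36.1 ± 2.50 against 30.3 ± 3.08 CPM. Car2 and Hba-a1, in the erythroid and platelet list, had 15.4 ± 1.37 against 12.98 ± 0.906 CPM and 0.476 ± 0.278 against 0.671 ± 0.458 CPM. Pecam1, listed as an endothelial marker but expressed by B cells, fell to 234 ± 15.04 from 278 ± 10.1 CPM. The camera adjusted p of the myeloid, dendritic and erythroid lists were 0.986, 0.32 and 0.931 with Benjamini-Hochberg adjustment, and the T cell, natural killer, stromal and sex-linked lists had fewer than 5 tested members. Adjusted over the list alone, 1 myeloid marker was higher and 1 lower, 1 natural killer and 1 stromal marker were lower, and 0 passed in the T cell, dendritic, erythroid and sex-linked lists. The call of Pecam1 was lost with upper-quartile factors, those of Itgam and Pecam1 were lost without any library except GFP-ZFP36L1 replicate 1, and without that library 2 myeloid markers and 1 natural killer marker were called. In the T cell, natural killer, dendritic, erythroid and sex-linked lists edgeR's quasi-likelihood test called 0 genes, with 1, 1, 2, 1 and 1 at an unadjusted p under 0.05, 0, 1, 0, 0 and 0 by DESeq2 and 1, 0, 2, 0 and 0 by limma voom. The Y-linked gene Eif2s3y had 125 ± 17.1 CPM in the labelled libraries and 145 ± 7.47 CPM in the controls.

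Genes with UAUUUAU heptamers in the 3' UTR did not pass as a group by camera. Of 10955 tested genes with a 3' UTR, 3250 held at least 1, and their median log2 fold change was 0.00543 against -0.00575 for the others (camera p = 0.685, and 0.781 with an estimated correlation). Over 5 groups of 2191 genes ordered by 3' UTR length, the median log2 fold change went from -0.0425 in the shortest to 0.0316 in the longest. Within each group, genes with the heptamer had the lower median, -0.0648 against -0.0411 in the shortest and 0.0275 against 0.0374 in the longest. Against 10000 draws matched on 3' UTR length and expression, the median of heptamer genes was lower (0.00543 against a median of 0.0126 over draws), with a one-sided share of 1e-04, the smallest the draws can give. Matched on expression alone the share was 1. The matched z is the distance of a set's mean log2 fold change, not its median, from the mean over draws, in SD of the draws. Among the 21 orders of 5 T and 2 A, TATTTAT had the lowest matched z, -2.1, ahead of TTATTTA at -1.32. Several other orders lay farther from 0 on the upper side, with ATATTTT at 4.07 and TTTTATA at 4.26. Of genes called lower, 36.2% held a heptamer, against 30.6% of genes called higher and 29.6% of genes not called (Fisher's exact test for lower against not called, p = 0.0888, two-sided).

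**Figure D4:**
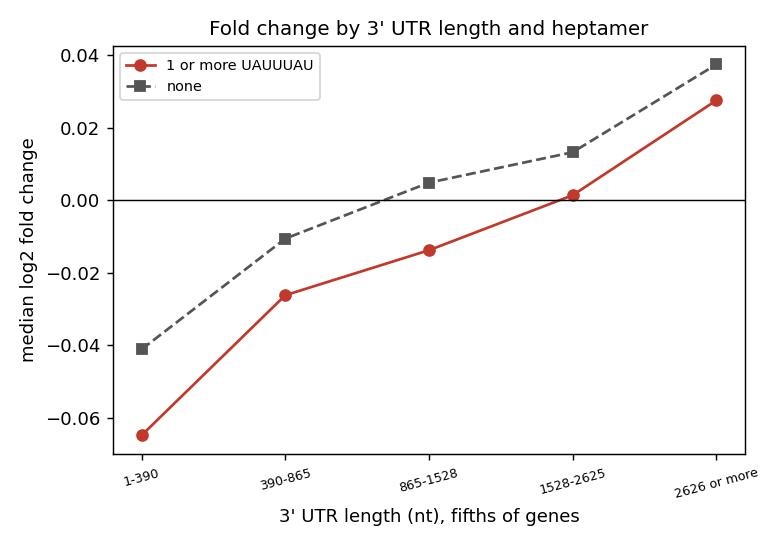
Median log2 fold change, libraries labelled GFP-ZFP36L1 over control, of tested genes with at least 1 UAUUUAU (circles) and with none (squares), in 5 groups of 2191 genes by 3' UTR length in nt. Medians are higher in the groups of longer 3' UTRs, and in the longest they are 0.0275 and 0.0374.

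The authors' deposited table was compared with the fit from counts. In it, 875 genes had an adjusted p under 0.05, 496 higher and 379 lower, and these included all 407 genes called here, in the same direction. Zfp36l1 was lower in the authors' deposited table, at a log2 fold change of -0.29, and Gt(ROSA)26Sor was at -1.55. The fit from counts gave -0.32 and -2.11. Whether the deposited fold changes were reduced in size by shrinkage is not given in the sources used here, so their sizes may not be comparable. Across 13035 genes, which are not independent replicates, the log2 fold changes had a Pearson's r of 0.886 and a Spearman's rho of 0.98.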

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

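The tests of swapped labels, of changes across a whole locus and of an extra gene copy were chosen after the results were seen. The split of the 8 libraries by label gave 407 genes past the threshold in edgeR's quasi-likelihood test, and the highest of the other 34 splits gave 7. It was the sole split of 35 (1 of 35) with as many, which is the smallest share these splits can give. A random division of the libraries is thus argued against for this count, but not excluded. The order of the sample titles was left out of account.

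Among 242 groups of 4 libraries examined, 11 held a library set apart from the other 3 by Dixon's gap ratio, where about 1 in 20, or 12.1, are due by chance. In the controls these were replicate 1 for Zfp36l1 (ratio 0.85, 599 CPM against 523 to 535), Lfng (0.867, 64.6 CPM against 52.2 to 53.9) and Lat (0.89, 2.12 CPM against 1.37 to 1.45), replicate 2 for Asb2 (0.93, 0.724 CPM against 1.09 to 1.12), and replicate 3 for the interferon score (0.845, 4.60 against 4.35 to 4.39). In the libraries labelled GFP-ZFP36L1 these were replicate 1 for Abi2 (0.848, 6.88 CPM against 8.55 to 8.85), Ccr6 (0.845, 103 CPM against 62.9 to 69.2), Ldha (0.938, 188 CPM against 147 to 150) and Igkv4-58 (0.935), and replicate 4 for Kif13a (0.844, 13.8 CPM against 7.39 to 8.39) and Ankrd37 (0.834, 7.04 CPM against 10.7 to 11.4).

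In the libraries labelled GFP-ZFP36L1, Zfp36l1 was lower, as was Gt(ROSA)26Sor at the Rosa26 locus, and Trappc5, beside the gene for CD23, was higher. A swap of labels between the groups is argued against, since 0 libraries had Gt(ROSA)26Sor in the range of the other group, and a change of either whole region by the amount of these genes is too. The other 16 tested genes within 500 kb of Gt(ROSA)26Sor had a median log2 fold change of -0.0378 (SD 0.108, from -0.2846 to 0.1623), and the 16 around Trappc5 had -0.0312 (SD 0.27, from -0.4959 to 0.621). A change of a few genes there stays open, as Ttll3 near Rosa26 (-0.2846, adjusted p 0.0447) and Pex11g near Trappc5 (0.621, adjusted p 0.0486), picked after their values were seen, were called. The call of Ttll3 was lost without any library except control replicate 1 and that of Pex11g without any except GFP-ZFP36L1 replicate 1, at adjusted p of up to 0.148 for each. An extra copy of Trappc5 carried with the CD23 Cre construct may account for its rise, as its fold of 1.49 (1.35 to 1.64 at 2 SE) covers the 1.5 of 3 copies against 2, but the makeup of the construct was not given and the idea came from the same value, so this stays open. A reversal of every label, counting that leaves out transcripts of the allele, and action of the protein on the 3 heptamers of its own mRNA stay open for Zfp36l1, and none was tested.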

How the results depend on the processing

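Removal of the trend with transcript length and GC and the title number as a linear term were chosen after the data were seen. Of 53 named genes called, 21 were called under every alternative and 0 changed sign. Of 54 not called, 39 passed under at least 1 alternative. The count of 407 (238 higher, 169 lower) became 882 (499, 383) with DESeq2, 1064 (569, 495) with limma voom and 1315 (655, 660) with 1 surrogate variable, 1030 (523, 507) with the title number as a linear term, and the length and GC correction gave 259 lower. With 1 library left out it ran from 79 to 948 (52 to 536 higher, 27 to 412 lower), and Zfp36l1 ran from -0.34 to -0.27, and of these 8 fits only that without GFP-ZFP36L1 replicate 1 called it. The count of 10 lists became 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 2 with fry. Fry called the reported targets and the genes around Rosa26, and camera had not called the latter, a list that includes Gt(ROSA)26Sor. The count was 8 with the title number, and with 1 library left out it ran from 6, without GFP-ZFP36L1 replicate 4, to 11. Heptamer genes had a camera p of 0.365 to 0.998 under the alternatives run. Spearman's rho with the authors' table became 0.925 with limma voom. It was 0.787 with DESeq2 and 0.781 with no filter, fits that kept genes the main filter removes, so the sets of genes differ. Signs turned for Cd93 (-0.0086 with 1 surrogate variable, -0.03301 with the title number, and with 1 library left out -0.051, without GFP-ZFP36L1 replicate 4, to 0.22), Hba-a1 (-0.89 to 0.081, the latter without control replicate 4), the V segments (adjusted p = 0.147 after the length and GC correction) and the heptamer median (0.0105 above draws without matching on 3' UTR length). The labels do not say what the title numbers stand for. Libraries of equal rank by title number in both groups had correlations of 0.0502 to 0.376 in their deviations from the group means, and 6 of the 8 correlated best with the library of their own rank. In both groups, principal components 1 and 2 and the TMM factor had rank correlations of 1, -1 and 1 with the title number. The labels do not explain this order, and the main test and the exact permutation tests took no account of it. The cause of the shifts between alternatives was not tested. Counts limit precision for genes near 1 CPM, such as Cxcr3 and Asb2.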

Other observations

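The test on neighbouring genes and the removal of the length and GC trend were chosen after results were seen. Called genes lay side by side more often than shuffled ones: 27 pairs of neighbouring tested genes were both called, against a mean of 12.7 and a highest of 29 over 10000 shuffles (share 3e-04), and 24 of them moved the same way. Among pairs picked after their values were seen were the lysosomal channel genes Mcoln3 and Mcoln2, with log2 fold changes of 0.83 and 0.56, and the membrane protein genes Tmem176b and Tmem176a, with 0.62 and 0.66. Neurl2, Ctsa and Pltp, which overlap or adjoin on chromosome 2, had -0.80, -0.24 and -0.77. Overlapping neighbours can share reads, and no explanation was tested.

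For gene lists, the pattern is a set of 10 called by camera at a preset correlation of 0.01, 9 of them lower, and 0 were called with an estimated correlation. The split by label was not unusual in that number, as 4 of 35 splits gave as many lists and the highest other gave 11, and 2 of 35 gave as many by fry, the highest other giving 2, so chance could not be excluded for either number. Set against the splits list by list, the median was farthest from 0 under the real labels for follicular (0.256 in size, highest other 0.214), interferon (0.52, highest other 0.495), immunoglobulin constant (0.265, highest other 0.218) and B cell receptor genes (0.0788, highest other 0.0758), each 1 of 35, in a test run on 29 lists. For follicular and constant genes the library scores had an exact permutation p of 0.0286 too, the smallest that 4 against 4 libraries can give. After Benjamini-Hochberg adjustment over the 29 lists it was 0.138, so chance could not be excluded for them. Chance also stays open for interferon and B cell receptor genes, whose scores had 0.0571 and 0.2 in that test, or 0.207 and 0.437 adjusted. By the median, it could not be excluded for antigen presentation (3 of 35, highest other 0.139), migration (5, 0.16), ribosomal (11, 0.237), V segment (12, 0.112), oxidative phosphorylation (13, 0.192) and reported target genes (14, 0.0917), though the scores of the migration and target lists also had an exact p of 0.0286, which leaves these open as well. The splits took no account of the order of the sample titles. A trend with transcript length and GC as the whole cause is argued against for 4 lists, since after its removal the medians were -0.25 for follicular, 0.524 for interferon, -0.11 for ribosomal and -0.0761 for oxidative phosphorylation genes and all 4 were still called by camera at the preset correlation, though none was called with an estimated one even before the removal (adjusted p 0.532, 0.708, 0.902 and 0.902). The V segment list lost its call and turned from -0.0598 to 0.0142 (adjusted p 0.147), so the trend stays open for it. A lower follicular and a higher interferon program in these cells stay open as hypotheses, and the design does not separate Cre from the protein.

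For heptamer genes, the pattern is a median below that of genes with 3' UTRs of like length. As length is already matched in that pattern, the matched share is no test of length as its cause. Both matched shares were 1e-04, but the draws treat genes as independent, so the share matched on AT content does not settle it as a cause. TATTTAT ranked 1 among 21 orders, but some order must rank first, so the rank cannot tell whether the other orders were lowered too. A lowering shared by all heptamers of 5 T and 2 A is argued against by the matched z of the other orders. It lay above 0 in ranks 4 to 21, from 0.0165 to 4.26. Other orders lay farther from 0 on the upper side, up to a matched z of 4.26, so a shift of this size is not particular to the motif. Chance could not be excluded: 10 of 35 splits of the libraries gave a matched z, which rests on the mean, as far from 0 as 2.12, up to 4.15. For the unmatched camera test 33 of 35 gave a p as small as 0.685, the lowest being 6.83e-05. A weak effect of the labelled protein on mRNAs with its motif therefore stays a hypothesis.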
